A study of Homo sapiens with 12 samples.

How the data were processed

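RNA sequencing of 12 MCF10AT libraries was used, 3 each from the non-silencing controls NS1 and NS2 and from the EP300 shRNA lines EP300 KD1 and EP300 KD2. Per the labels' protocols, cells were transduced with lentiviral shRNA particles and selected with puromycin, RNA was isolated with Trizol, and libraries were made with a stranded Illumina TruSeq mRNA kit. Per the submitters' processing notes, the authors aligned reads with HISAT2 2.1.0 to hg38 and counted them with featureCounts. The counter's version, the annotation release and the strand and multi-mapping settings are not given in the sources used here. The deposited values are whole-number counts, not normalised, for 29094 RefSeq transcript accessions, 1 column per library, with totals from 31396653 to 45606950. The labels do not say whether the 3 replicates of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

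Each accession row was analysed as deposited and is called a gene below. Symbols came from a RefSeq gene table for the same assembly (28134 accessions) and from a GENCODE transcript table (452 more), and 508 accessions, with 0.315% of all counts, had no symbol. Coordinates are those of the RefSeq gene table on GRCh38 (hg38), 1-based. For 2308 symbols the table holds more than 1 accession row. Those 5920 rows carry only 0.972% of all counts, and coding symbols with several rows had a median total of 47 counts over all 12 libraries, against 3386.5 for coding symbols with a single row. Counts of such genes are therefore residual and uncertain, and a fit without them was added. Coding genes of the MHC region on chromosome 6 likewise had a median total of 33 counts, so that values of HLA genes are uncertain.

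Replicates were compared before averaging: in every pair within a group, counts differed by more than sampling noise (chi-square per degree of freedom 1.86 to 4.54). All 12 libraries were kept as separate samples, although such spread does not show that they came from separate cultures. Genes were filtered with edgeR's filterByExpr at its default settings, which left 13424, and libraries were scaled by TMM. The model was edgeR's quasi-likelihood fit with 1 coefficient per group over all 12 libraries, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Contrasts were EP300 KD1 against NS1, EP300 KD2 against NS2, the average of both, their difference, and NS2 against NS1. Standard errors of log2 fold changes were derived from the test statistic. Levels are TMM-scaled CPM (counts scaled to library size) with the SD over 3 libraries. The common biological coefficient of variation was 0.030, which makes small changes detectable.

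The 33 gene lists, covering pathways, mammary cell states and markers of other cell types, were written before the data were examined, as were the design, the first set of alternative settings and the rule for the genes named. For the mitochondrially encoded genes no row was tested, which left 32 lists. Lists were tested with limma's camera on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01 and adjustment over the 32 lists of a comparison, then with a correlation estimated per list, and with fry, which asks whether a list's genes move on balance one way without comparing them with other genes. Members were counted from the adjusted p over all genes and again with p adjusted over the list alone.

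Genes were named by rule. EP300 and CREBBP were always named. Among genes called in the same direction by both hairpins, with at least 1 CPM on average and all libraries separated in both sets, the 12 up and 12 down with the largest smaller change were taken. For each hairpin the 5 most changed genes in each direction were added, and for the controls 3 in each direction. These too had at least 1 CPM on average and all libraries of their comparison separated. For the difference, the 5 in each direction were taken among genes of at least 1 CPM called in opposite directions. From each list described, up to 4 members with the smallest p were named. Pseudogenes and rows without a symbol were passed over. A list member that this rule selects is not reported here. HRAS, LY6E, EEF1D, U2AF1 and CD99 fall outside this rule and were chosen after their values were seen.

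The procedure was tested on simulated counts drawn from the means of these libraries with 13251 genes tested. For EP300 KD1 against NS1 it called 92% of genes changed 2-fold in the right direction, 68% at 1.5-fold, 56% at 1.25-fold and 28% at 1.1-fold, and 0.0907% of unchanged genes. For EP300 KD2 against NS2 the shares were 94%, 66%, 58% and 26%, with 0.0762% of unchanged genes. On unchanged simulated counts camera called 0 of 160 list tests. Simulated genes were drawn independently of each other, and most were left unchanged. The simulation therefore cannot show how often camera with the preset correlation calls a list whose members vary together. Alternatives covered other scalings and filters, DESeq2, limma-voom, stricter thresholds, only the libraries compared, pooled or swapped controls, the replicate number as a block, each library left out in turn, and, added after seeing the data, library totals without TMM, symbols with a single accession, and lines as replicates. R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and Python 3.11.15 were used. Intervals and floors from counts cover counting error only.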

Results

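Messenger RNA was measured by RNA sequencing in MCF10AT, an established line of human mammary epithelial cells transformed with an activated HRAS. Stable lines had been made with lentiviral shRNAs against EP300, the acetyltransferase p300 that acts as a transcriptional coactivator, or with non-silencing control hairpins. The 12 libraries fall into 4 groups of 3 replicates: EP300 KD1 and EP300 KD2, each made with a different EP300 hairpin, and the controls NS1 and NS2. The labels give each hairpin a corresponding control without naming it, and the control of the same number was taken as such here. Total counts per library ran from 32674926 to 45606950 in NS1, from 31396653 to 35024772 in EP300 KD1, from 32112613 to 33951970 in NS2 and from 31582157 to 40700951 in EP300 KD2 (n = 3 each). Of the variance among libraries, 58.6% lay on a first principal component that separated all 6 EP300 shRNA libraries from all 6 controls, and 18.7% on a second that separated EP300 KD1 from EP300 KD2.

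The knockdown target was examined first in every library. EP300 (NM_001429; chromosome 22, 41092592 to 41180077, hg38) measured 172 ± 5.11 CPM (read counts scaled by TMM to the library size) in NS1 and 107 ± 0.884 in EP300 KD1 (SD, n = 3), leaving 62.4% ± 0.514 of the control level. In the second set it measured 174 ± 8.14 CPM in NS2 and 95.8 ± 3.87 in EP300 KD2, leaving 55.0% ± 2.22. The SDs of both percentages cover the 3 shRNA libraries against the control mean and leave out the spread of the controls. Every EP300 shRNA library lay below every control library. The log2 fold changes were -0.68 ± 0.03 (SE, edgeR adjusted p = 2.6e-12) and -0.86 ± 0.04 (adjusted p = 1.1e-13), and EP300 fell further with the second hairpin (difference -0.18 ± 0.05, adjusted p = 0.0049). With library totals alone in place of TMM scaling, this difference was -0.11 and did not pass (adjusted p = 0.063). That alternative was chosen after seeing the data. CREBBP, the paralogue of EP300, measured 97.3 ± 2.50 and 95.4 ± 0.927 CPM in NS1 and EP300 KD1, and 101 ± 0.850 and 96.8 ± 4.22 in NS2 and EP300 KD2. Its log2 differences of -0.03 and -0.06 did not pass the test (adjusted p = 0.45 and 0.092). The second passed when EP300 KD2 replicate 2 was left out (-0.10, adjusted p = 0.010).

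**Figure D1:**
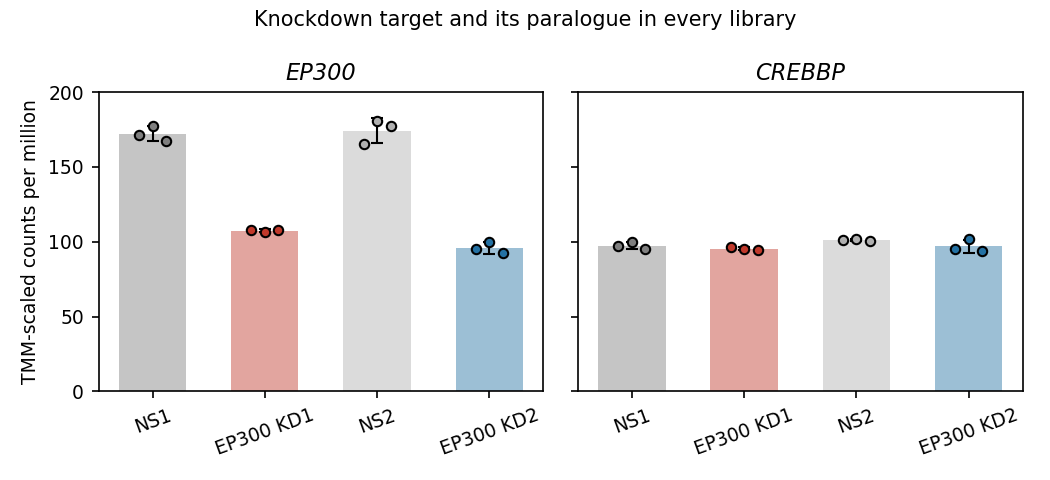
TMM-scaled CPM (vertical axis) of EP300 (left) and CREBBP (right) in the 4 groups; bars are means, error bars are SDs and points are single libraries (n = 3). EP300 means of 107 and 95.8 in the shRNA groups lie below control means of 172 and 174, while CREBBP means run from 95.4 to 101.

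The first comparison asked which transcripts changed with the first EP300 hairpin, EP300 KD1 against NS1. Losses and gains were ranked only among genes with at least 1 CPM on average and all libraries of the comparison separated. KRT15, a keratin of basal epithelium (NM_002275; chromosome 17, 41513745 to 41518890), dropped from 878 ± 19.9 to 47.6 ± 1.68 CPM (log2 -4.21 ± 0.03, edgeR adjusted p = 4.25e-24). The steepest losses were in kallikrein-related peptidases of chromosome 19 and in a mucin: KLK5 from 33.7 ± 1.72 to 0.371 ± 0.10 CPM, KLK10 from 6.17 ± 0.0297 to 0.0788 ± 0.0585, KLK7 from 25.3 ± 1.72 to 0.346 ± 0.123, MUC16 from 6.28 ± 0.207 to 0.0885 ± 0.0476 and KLK6 from 27.5 ± 1.59 to 0.498 ± 0.0136. The largest gains were in C3AR1, the receptor for complement fragment C3a (0.0426 ± 0.0369 to 4.65 ± 0.309), TNFAIP6, a hyaluronan-binding protein induced by cytokines (0.343 ± 0.0306 to 22.9 ± 2.15), the nicotinic receptor subunit CHRNA9 (0.222 ± 0.0780 to 9.46 ± 0.623), the surfactant protein SFTPB (0.199 ± 0.106 to 4.89 ± 0.713) and the growth factor receptor PDGFRA (0.430 ± 0.112 to 8.56 ± 0.551). Of 13424 genes tested, 8711 passed the test, 4370 of them higher and 4341 lower, and 1367 changed at least 2-fold (785 higher and 582 lower). The median absolute log2 change over all genes was 0.24, so that most calls were of small changes.

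Mesenchymal genes rose with the first hairpin. Of the 30 tested members of that list, 28 rose and 1 fell, with the same counts when adjusted over the list alone, and the median log2 change was 1.13 (camera adjusted p = 1.7e-11, and adjusted p = 0.0035 with an estimated correlation). FN1, the gene of fibronectin, rose from 80.5 ± 4.89 to 1149 ± 44.9 CPM, and VIM, the mesenchymal intermediate filament vimentin, from 548 ± 11.7 to 2164 ± 52.5. ITGA5, a subunit of the fibronectin receptor, rose by 2.04 on the log2 scale and the collagen gene COL6A3 by 4.19. The list of fibroblast markers, which was included as a check for other cells, moved the same way: 7 of its 8 tested members rose, with a median of 1.41 (camera adjusted p = 0.0087, but adjusted p = 0.070 with an estimated correlation). Its members DCN and C1R rose by 2.57 and 2.72, whereas FBLN1 had a log2 change of -1.95. The fibroblast and mesenchymal lists name some of the same genes, so their changes need not be independent.

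Junction and luminal genes fell with the first hairpin. Of 31 tested members of the list of epithelial junction and polarity genes, 25 fell and 2 rose, also when adjusted over the list alone, with a median of -0.49 (camera adjusted p = 4.1e-08, and adjusted p = 0.0035 with an estimated correlation). CLDN1, a tight junction protein, had a log2 change of -2.90, the epithelial transcription factor GRHL2 -1.12 and the vesicle GTPase RAB25 -0.82. CDH1, the gene of E-cadherin, dropped from 383 ± 7.75 to 211 ± 0.744 CPM. Among 18 tested luminal mammary markers, 16 fell and 2 rose, with a median of -1.21 (camera adjusted p = 1.2e-06, and adjusted p = 0.018 with an estimated correlation), and the counts were identical when adjusted over the list alone. ELF3, an epithelial transcription factor, had a log2 change of -2.49, AGR2, a disulfide isomerase of secretory cells, -4.15 and the mucin MUC1 -1.62, while the EGF receptor ligand AREG went the other way (1.1). Basal mammary markers were not called as a list (12 of 21 fell and 6 rose, adjusted p = 0.094), nor were squamous differentiation genes (14 of 23 fell and 7 rose, adjusted p = 0.084), although KRT17, DST, TRIM29 and KRT5 had log2 changes of -1.24, -1.13, -1.21 and -0.71.

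Inflammatory genes rose and replication genes fell. In the list of NF-kB targets and cytokines, 25 of 27 tested members rose and 1 fell, with the same counts when adjusted over the list alone (median 1.71, camera adjusted p = 2.2e-10, and adjusted p = 0.049 with an estimated correlation). The cytokine genes IL1B and IL1A rose by 3.29 and 2.32 on the log2 scale, the mitochondrial superoxide dismutase SOD2 by 2.17 and the chemokine CCL20 by 2.15. The list of leukocyte markers, included as a check for other cells, had 4 of 7 tested members higher and 1 lower. It was not called by camera (adjusted p = 0.12), though it was by fry (adjusted p = 1.3e-06). Of 37 tested genes of S phase and DNA replication, 36 fell and 0 rose, again also when adjusted over the list alone (median -0.68, camera adjusted p = 2.4e-15, and adjusted p = 0.018 with an estimated correlation). The replicative helicase subunits MCM3 and MCM7 had log2 changes of -1.11 and -0.62, the transcription factor E2F2 -2.20 and DTL, a factor of replication control, -0.90. Genes of G2 and mitosis were not called as a list (22 of 41 fell and 6 rose, median -0.06, adjusted p = 0.091). Calls that were lost with an estimated correlation were a rise of the hypoxia and glycolysis list (23 of 38 rose and 9 fell, camera adjusted p = 0.0038, adjusted p = 0.37 with an estimated correlation), with ANGPTL4 up by 1.84 and the glucose transporter SLC2A3 up by 3.13, and a rise of TGF-beta and SMAD targets (15 of 26 rose and 7 fell, camera adjusted p = 0.038, adjusted p = 0.31 with an estimated correlation). In the latter list COL4A1 and TGFB1 rose by 1.92 and 2.05 and TGFB2 had a log2 change of -2.32. Ribosomal protein genes were slightly lower (47 of 49 fell and 0 rose, or 48 fell when adjusted over the list alone, median -0.18, camera adjusted p = 4.1e-08, adjusted p = 0.20 with an estimated correlation).

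The second comparison asked the same of the other hairpin, EP300 KD2 against NS2. Gains and losses were again ranked only among genes with at least 1 CPM on average and separated libraries. KRT15 dropped from 691 ± 17.4 to 37.7 ± 1.30 CPM (log2 -4.19 ± 0.03, edgeR adjusted p = 6.1e-24), KLK5 from 17.7 ± 0.492 to 0.624 ± 0.114 and KLK6 from 13.2 ± 1.28 to 0.533 ± 0.0623. ATP6V1B1, a subunit of the proton-pumping vacuolar ATPase, went from 1.90 ± 0.0672 to 0.0378 ± 0.0416, PHACTR3, a regulator of protein phosphatase and actin, from 1.57 ± 0.167 to 0.0512 ± 0.0381, and the FERM-domain gene EPB41L4A from 27.9 ± 0.925 to 1.14 ± 0.184. The largest gains were in CORO2B, an actin-binding coronin (0.235 ± 0.0416 to 4.33 ± 0.663), SLFN11, a schlafen-family gene linked to replication stress (0.379 ± 0.0912 to 4.78 ± 0.609), RAB3B, a GTPase of regulated secretion (0.369 ± 0.149 to 4.22 ± 0.308) and the scavenger receptor family gene SCARA3 (0.299 ± 0.102 to 3.31 ± 0.0269). MIF was also among them (log2 3.56, adjusted p = 0.0029), but 1 library decided this value. MIF measured 44.0 CPM in EP300 KD2 replicate 2 and 1.36 and 1.40 in the other two, and without that library its log2 change was 0.07 (adjusted p = 0.81). DESeq2 gave no adjusted p for it, and limma-voom did not call it. In all, 7762 genes passed the test, 3744 higher and 4018 lower. This balance depended on scaling. With upper-quartile factors it was 4630 higher and 3358 lower. With library totals alone it was 4979 higher and 3144 lower. At least 2-fold changes were called for 1085 genes, 396 higher and 689 lower.

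Epithelial lists fell with the second hairpin, and here the basal and squamous lists were called too. Of 31 junction and polarity genes 28 fell and 0 rose, also when adjusted over the list alone (median -0.59, camera adjusted p = 8.8e-12, and adjusted p = 0.0016 with an estimated correlation). CLDN1 had a log2 change of -2.16, the desmosomal cadherin DSG3 -1.33 and the tight junction scaffold TJP3 -2.94, and CDH1 dropped from 377 ± 3.75 to 181 ± 1.71 CPM. Of 18 luminal markers 13 fell and 0 rose, or 14 fell when adjusted over the list alone (median -0.92, camera adjusted p = 1.5e-06, and adjusted p = 0.020 with an estimated correlation), with SLPI, a secreted protease inhibitor, at -2.11, AGR2 at -4.32 and MUC1 at -2.15. Of 21 basal markers 18 fell and 1 rose, or 2 rose when adjusted over the list alone (median -0.74, camera adjusted p = 8.3e-08, and adjusted p = 0.027 with an estimated correlation). The basal keratins KRT17 and KRT5 had log2 changes of -1.99 and -1.26, the hemidesmosomal collagen COL17A1 -1.55 and the cytoskeletal linker DST -1.41. In the squamous differentiation list 15 of 23 tested members fell and 1 rose, or 16 fell when adjusted over the list alone (median -0.91, camera adjusted p = 3.4e-05, and adjusted p = 0.020 with an estimated correlation), led by KLK5, KLK6, KLK7 (-4.17) and KRT16 (-2.47).

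Cell cycle genes rose with the second hairpin. All 41 tested genes of G2 and mitosis rose, also when adjusted over the list alone (median 0.40, camera adjusted p = 1.3e-16, and adjusted p = 0.030 with an estimated correlation). CDC20, DLGAP5, the checkpoint kinase BUB1 and FOXM1, a transcription factor of mitotic genes, rose by 0.59, 0.64, 0.59 and 0.57. Of 37 genes of S phase and DNA replication, 36 rose and 0 fell, or 37 rose when adjusted over the list alone (median 0.43, camera adjusted p = 3.5e-14, and adjusted p = 0.020 with an estimated correlation). RRM2, a subunit of ribonucleotide reductase, rose by 0.74 and the helicase subunits MCM4, MCM7 and MCM5 by 0.54, 0.42 and 0.52. NRF2 targets fell (19 of 23 fell and 2 rose, also when adjusted over the list alone, median -0.40, camera adjusted p = 4.4e-06, and adjusted p = 0.020 with an estimated correlation), among them the cystine transporter SLC7A11 (-1.39) and the aldo-keto reductases AKR1C3 (-1.23) and AKR1C2 (-1.47). AKR1C2 and AKR1C3 are related genes for which the counting can misassign shared reads.

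Mesenchymal and inflammatory genes moved less uniformly with the second hairpin. Of the 30 mesenchymal genes 16 rose and 9 fell, or 17 rose when adjusted over the list alone (median 0.36, camera adjusted p = 0.0064, but adjusted p = 0.090 with an estimated correlation). FN1 rose from 86.5 ± 5.11 to 389 ± 2.92 CPM and VIM from 612 ± 12.2 to 1513 ± 18, N-cadherin (CDH2) rose by 1.57 on the log2 scale and the receptor kinase AXL by 0.49. Of 8 fibroblast markers 4 rose and 1 fell, and the list was not called (camera adjusted p = 0.27). NF-kB targets and cytokines rose in 19 of 27 cases and fell in 4 (median 0.34, camera adjusted p = 0.00094, but adjusted p = 0.20 with an estimated correlation), with PTGS2 and IL6 up by 1.78 and 1.71 and TNFAIP2 and BIRC3 at -0.81 and -0.59. Further lists lost their call with an estimated correlation. The unfolded protein and ATF4 response list fell in 17 of 26 members and rose in 5, or 18 and 6 when adjusted over the list alone (camera adjusted p = 4.1e-05, adjusted p = 0.13 with an estimated correlation), with the serine synthesis gene PSAT1 at -1.02. RAS and MAPK output genes fell in 16 of 25 and rose in 3 (median -0.20, camera adjusted p = 0.0071, adjusted p = 0.20 with an estimated correlation), with the EGF receptor ligand HBEGF at -1.97. Against both controls pooled, 13 of these fell and 10 rose, with a median of -0.06. Notch pathway genes fell in 10 of 17 and rose in 5 (camera adjusted p = 0.035, adjusted p = 0.20 with an estimated correlation), with the ligand JAG1 at -1.05. Fatty acid synthesis genes fell in 11 of 17 and rose in 2 (camera adjusted p = 0.015, adjusted p = 0.074 with an estimated correlation). Ribosomal protein genes fell in 38 of 49 and rose in 0 (median -0.14, but -0.09 with upper-quartile factors and -0.08 with library totals alone, camera adjusted p = 4.4e-06, adjusted p = 0.20 with an estimated correlation). The list of HEK293 and neural-type genes was included as a check for other cells. Its 5 tested genes rose in 4 cases and fell in 1 (camera adjusted p = 0.039, adjusted p = 0.13 with an estimated correlation), with the neuronal tubulin TUBB3 up by 1.5.

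**Figure D2:**
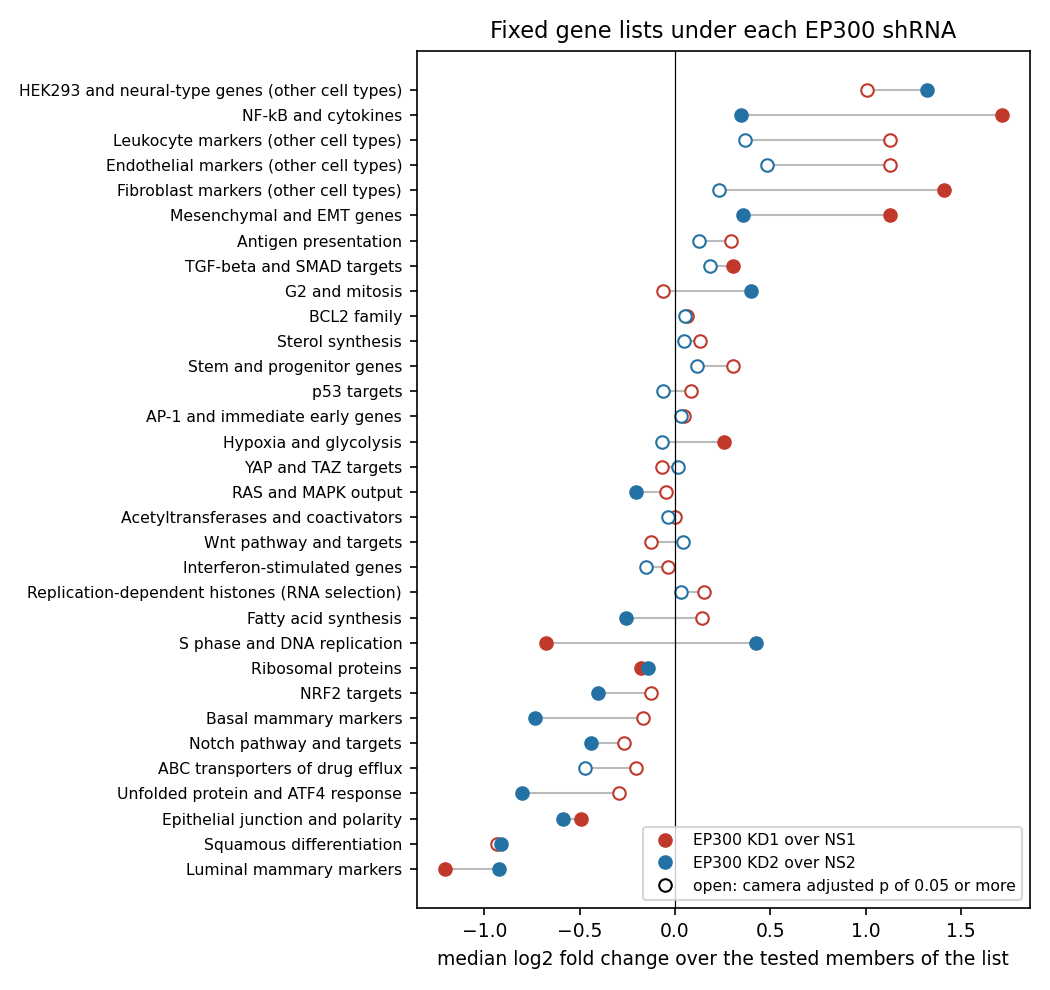
Median log2 fold change over the tested members of each fixed gene list (horizontal axis) for EP300 KD1 over NS1 (red) and EP300 KD2 over NS2 (blue), with a line joining both; filled points have a camera adjusted p under 0.05 with the preset correlation. Genes of S phase and DNA replication lie at -0.68 for the first hairpin and at 0.43 for the second, while the luminal list lies at -1.21 and -0.92.

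The genes that changed the same way with both hairpins were taken next, since each hairpin had its own control and the comparisons share no library. Among the shared losses, the log2 changes with the first and second hairpin were -5.34 and -4.62 for EPB41L4A, -4.48 and -4.48 for the villin-like gene VILL, -4.78 and -4.21 for the mucin glycosyltransferase GCNT3, -4.64 and -4.20 for PLEKHS1, -4.21 and -4.19 for KRT15 and -4.15 and -4.32 for AGR2. The list also held ATP6V1B1 (-5.09 and -5.58), KLK5 (-6.50 and -4.82), PHACTR3 (-5.07 and -4.77), KLK6 (-5.78 and -4.62), KLK10 (-6.22 and -4.61) and KLK7 (-6.17 and -4.17). ATP6V1B1, PHACTR3, KLK10 and PLEKHS1 were near the floor in both shRNA groups (means from 0.0378 to 0.123 CPM), so the sizes of their losses are uncertain. The shared gains were led by CORO2B (3.57 and 4.17), RAB3B (3.21 and 3.5), C3AR1 (6.59 and 3.18), SYDE1 (3.04 and 2.99), SLFN11 (2.84 and 3.64) and the chromatin reader SP140 (2.88 and 2.64). They also held BRSK1 (3.69 and 2.62), TNFAIP8L3 (2.83 and 2.56), CHRNA9 (5.44 and 2.52), the annexin ANXA6 (2.94 and 2.34), the 5-lipoxygenase activating protein ALOX5AP (2.34 and 2.48) and the neurexin relative CNTNAP2, which rose from 10.8 ± 0.371 to 71.0 ± 3.71 and from 14.8 ± 0.369 to 84.8 ± 3.10 CPM. In these genes every EP300 shRNA library lay on one side of every library of its own control.

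Both hairpins together called 4380 genes in the same direction, 2051 up and 2329 down, where independent lists would share 1219 and 1299. With upper-quartile factors the split was 2513 up and 1994 down. With library totals alone it was 2526 up and 1984 down. A further 1500 genes were called in opposite directions. With a 2-fold change required in both, 673 genes were shared, 276 up and 397 down against 23.2 and 29.9 for independent lists, and 13 were opposite. Across the 13424 genes, which are not independent replicates, the log2 changes of both hairpins had a Pearson correlation of 0.70 and a Spearman correlation of 0.45, with a slope of 0.59 for the second on the first. Without a filter on low counts the Pearson correlation was 0.37. The average of both responses was called for 8821 genes, 4377 up and 4444 down. The split was 5103 up and 3782 down with upper-quartile factors. It was 5091 up and 3796 down with library totals alone. By list, 13 of 32 tested lists were called. Of those 13 lists, the fall of luminal markers and of junction genes and the rise of mesenchymal genes also held with an estimated correlation (adjusted p = 0.021, 0.0022 and 0.013). The mesenchymal rise was uneven, with medians of 1.13 for the first hairpin and 0.36 for the second. With the second, 16 of 30 rose and 9 fell (camera adjusted p = 0.090 with an estimated correlation). For the average, the fibroblast marker list was called higher too (7 of 8 up, camera adjusted p = 0.020), but not with an estimated correlation (adjusted p = 0.11). When counts were summed per line, so that the 2 EP300 shRNA lines were set against the 2 control lines with 2 residual degrees of freedom, 491 genes were called (150 up and 341 down), all 491 of them among the 4380. This alternative was chosen after seeing the data. In it EP300, VIM, CDH1 and KRT15 passed (adjusted p = 0.032, 0.032, 0.030 and 0.0093), whereas FN1, C3AR1, BRSK1, TNFAIP8L3 and CHRNA9 did not (adjusted p = 0.056, 0.096, 0.13, 0.11 and 0.075).

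**Figure D3:**
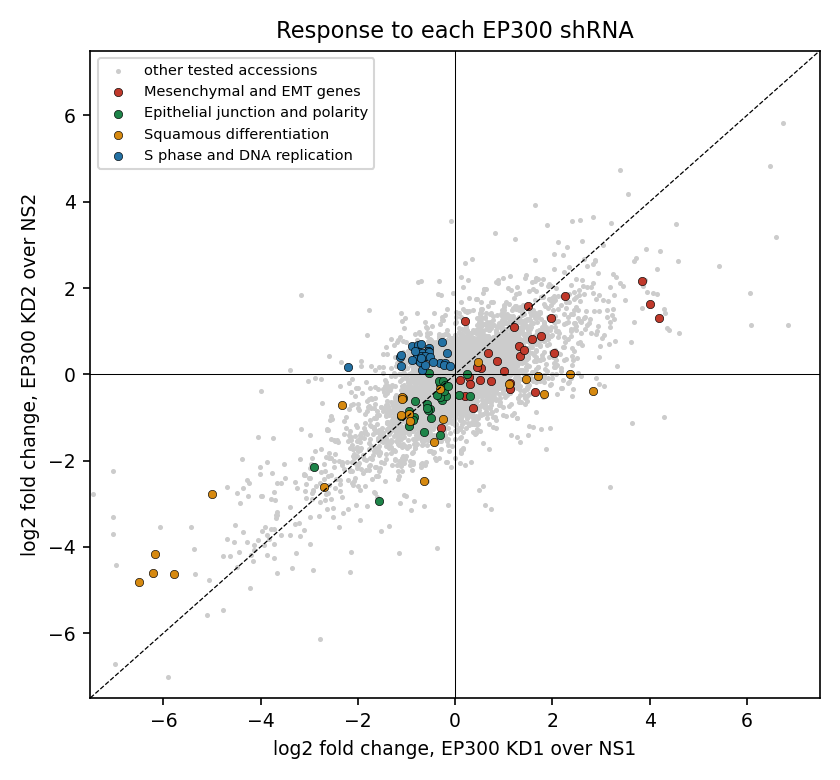
Log2 fold change of each tested gene for EP300 KD1 over NS1 (horizontal axis) against EP300 KD2 over NS2 (vertical axis), with members of 4 fixed lists coloured and the dashed line marking equal change; MIR30A is not drawn and 1 point lies outside the axes at 7.5. Replication genes (blue) lie in the upper left, with medians of -0.68 and 0.43.

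The difference between the responses was tested directly, as the second hairpin's change minus the first's. By camera with the preset correlation, replication and mitosis genes had the smallest p for this difference. All 37 tested genes of S phase and DNA replication lay higher in the second response than in the first (median difference 1.09, camera adjusted p = 5.5e-29, and adjusted p = 0.0073 with an estimated correlation), as did all 41 of G2 and mitosis (median 0.47, adjusted p = 6.3e-21, and adjusted p = 0.029 with an estimated correlation), also when adjusted over the list alone. Basal markers lay lower in the second response (17 of 21 lower and 2 higher, median -0.44, adjusted p = 2.0e-05, but adjusted p = 0.064 with an estimated correlation). The squamous list, which was called only with the second hairpin, was not called here by camera (adjusted p = 0.79). Its members differed in both directions: 10 of 23 lay lower and 7 higher, 8 and 5 of them at least 2-fold. By fry it was called lower (adjusted p = 0.00012). Mesenchymal genes lay lower in the second response (27 of 30 lower and 1 higher, median -0.74, adjusted p = 2.1e-09, and adjusted p = 0.0073 with an estimated correlation). Fibroblast markers, the check for other cells, lay lower too (7 of 8 lower and 1 higher, median -1.32, adjusted p = 0.0097, but adjusted p = 0.064 with an estimated correlation). So did fatty acid synthesis genes (12 of 17, or 13 when adjusted over the list alone, median -0.34, adjusted p = 6.8e-05, and adjusted p = 0.017 with an estimated correlation) and NRF2 targets (16 of 23, median -0.28, adjusted p = 7.2e-05, and adjusted p = 0.041 with an estimated correlation). For NF-kB targets and cytokines, 22 of 27 lay lower (median -0.92, adjusted p = 4.2e-09, but adjusted p = 0.060 with an estimated correlation). In all, 6818 genes differed, 2903 with a higher and 3915 with a lower second response, and with library totals alone the split was 3780 to 3117. At least 2-fold differences numbered 766.

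Among genes called in opposite directions, the telomerase gene TERT went from 1.35 ± 0.162 to 0.379 ± 0.118 CPM with the first hairpin and from 0.872 ± 0.152 to 1.62 ± 0.301 with the second (log2 -1.82 and 0.91). MNS1 (-1.26 and 0.68) and the sodium-calcium exchanger SLC8A1 (-1.06 and 0.78) also fell and then rose. The long non-coding RNA UCA1 (-2.60 and 0.43) and E2F2 (-2.20 and 0.16) were called likewise, but their rise with the second hairpin was not stable. It was no longer called by DESeq2 (adjusted p = 0.081 and 0.069). For UCA1 it was also lost without NS2 replicate 1, NS2 replicate 3 or EP300 KD2 replicate 3 (adjusted p = 0.17, 0.065 and 0.13), and for E2F2 without NS1 replicate 1, NS2 replicate 1, NS2 replicate 2, EP300 KD2 replicate 1 or EP300 KD2 replicate 3 (adjusted p = 0.050, 0.075, 0.17, 0.11 and 0.11). Against both controls pooled, the second response was -0.49 for UCA1 and -0.01 for E2F2. In the other direction, the formyl peptide receptor FPR1 went from 3.5 ± 0.308 to 13.5 ± 0.547 and from 4.25 ± 0.532 to 1.80 ± 0.111 CPM (1.94 and -1.24). The lipoxygenase ALOX15B (1.34 and -1.57), the myeloid receptor TREM1 (1.59 and -1.23) and ANKS1B (1.52 and -1.19) followed the same pattern. IL1A rose by 2.32 and had a second response of -0.19, which became 0.43 against both controls pooled, since NS2 held 36.2 ± 0.595 and NS1 15.3 ± 1.40 CPM.

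**Figure D4:**
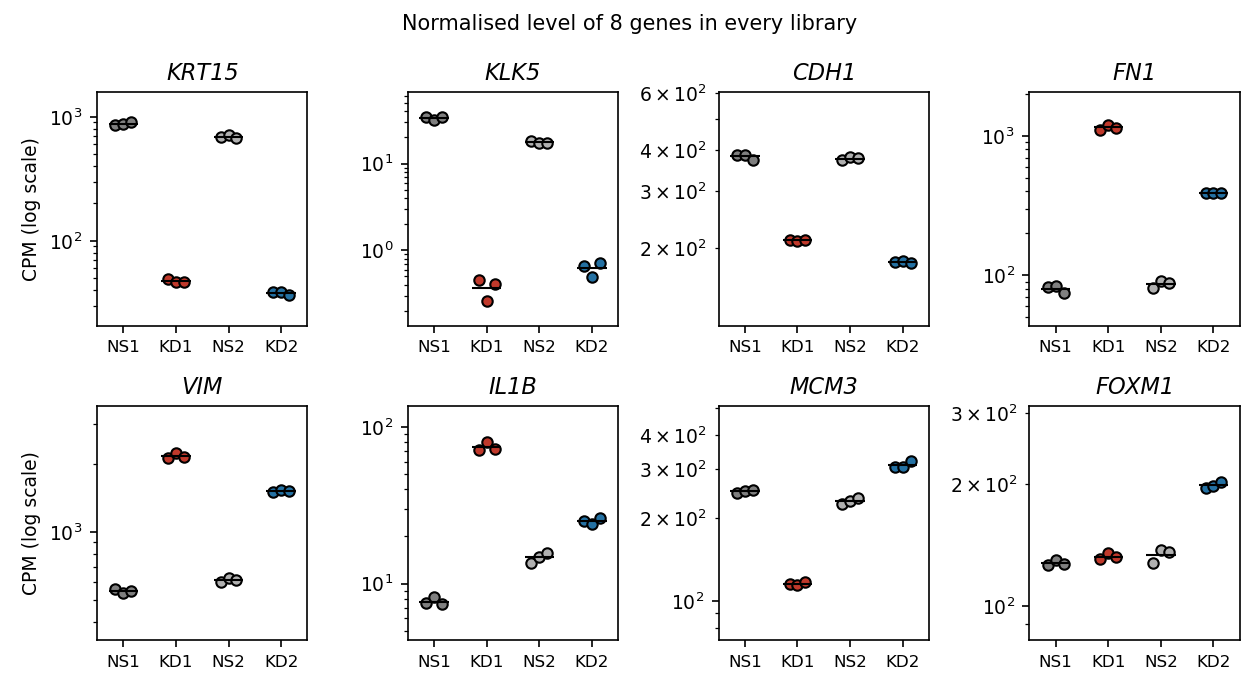
Normalised CPM of 8 genes (log-scaled vertical axes) in every library, by group; points are libraries and horizontal lines are group means (n = 3). KRT15, KLK5 and CDH1 lie lower and FN1, VIM and IL1B higher in both EP300 shRNA groups than in their controls, whereas MCM3 lies below its control in KD1 and above it in KD2.

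The controls were compared as the background for these differences, NS2 against NS1. IL13RA2, a decoy receptor for interleukin 13, and MEFV, the inflammasome protein pyrin, rose from 3.26 ± 0.440 to 11.2 ± 0.784 and from 1.57 ± 0.109 to 4.47 ± 0.320 CPM. LBH, a regulator of mammary progenitors, dropped from 1.06 ± 0.145 to 0.163 ± 0.0734, the metalloproteinase ADAMTS9 from 6.52 ± 0.735 to 1.48 ± 0.109 and the complement factor gene CFI from 8.65 ± 0.671 to 2.20 ± 0.0960. MIR30A stood apart from all of these: it had 0 reads in NS1 and 95.6 ± 5.97 CPM in NS2. Of 13424 genes 3697 differed, 1904 higher and 1793 lower in NS2. The split was 1587 higher and 2184 lower with upper-quartile factors. It was 1606 higher and 2157 lower with library totals alone. With TMM scaling, 174 genes differed at least 2-fold (14 higher and 160 lower). At an adjusted p under 0.01 the count was 2354. By list, unfolded protein and ATF4 response genes (18 of 26 higher and 0 lower, or 19 higher when adjusted over the list alone, median 0.21, camera adjusted p = 2.5e-09), RAS and MAPK output genes (13 of 25 higher and 1 lower, or 15 and 2 when adjusted over the list alone, median 0.20, adjusted p = 1.5e-06) and NRF2 targets (14 of 23 higher and 1 lower, median 0.15, adjusted p = 3.1e-05) were higher in NS2, each with an adjusted p = 0.094 with an estimated correlation. Squamous differentiation genes were lower (11 of 23 lower and 2 higher, or 13 lower when adjusted over the list alone, median -0.44, adjusted p = 0.0045, and adjusted p = 0.094 with an estimated correlation). G2 and mitosis genes (23 of 41 higher and 0 lower, median 0.07, adjusted p = 5.3e-06) were also higher in NS2. So were NF-kB targets and cytokines (13 of 27 higher and 3 lower, adjusted p = 0.0014) and fatty acid synthesis genes (8 of 17 higher and 1 lower, adjusted p = 0.013). Ribosomal protein genes (21 of 49 lower and 0 higher, or 26 lower when adjusted over the list alone, adjusted p = 1.3e-05) were lower. So were replication-dependent histones (4 of 14 lower and 1 higher, or 6 lower when adjusted over the list alone, adjusted p = 0.015), genes of S phase and DNA replication (9 of 37 lower and 2 higher, adjusted p = 0.035) and interferon-stimulated genes (10 of 30 lower and 2 higher, adjusted p = 0.037). Of the 11 lists called between the controls, 0 were called with an estimated correlation and 17 of 32 lists were called by fry.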

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

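The tests of the MIR30A reads and of the replication genes were chosen after those results had been seen; the counts over other splits of the libraries were planned. The response to the second hairpin differed from that to the first in 6818 genes by the test of the difference itself. Of 100 splits drawn that exchanged shRNA and control libraries within each set, the real one alone (1 split) gave as many, with 6818 genes against a highest other of 4026. The split that exchanges all labels of a single set was not among those drawn; it turns the difference into the average, with 8821 genes. For the average response the real split alone gave as many too (8821 genes, highest other 4026, 1 split). For genes called the same way by both hairpins it did as well (4380, highest other 0, 1 split). Splits that mix shRNA and control libraries widen the spread within groups, which by itself lowers their counts. With 1 line per hairpin, these splits cannot exclude chance differences between lines. Nor can an effect of the set on the response be told apart from that of the hairpin, since each set held 1 hairpin. For EP300 KD1 against NS1 (8711 genes, highest other 0), EP300 KD2 against NS2 (7762, highest other 0) and NS2 against NS1 (3697, highest other 0), the 10 possible splits are too few for a share under 0.05.

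The following named genes differed between the hairpins, given as the second log2 response minus the first. EP300 itself differed by -0.18, a call that was lost with library totals alone. Genes with the larger rise, or the smaller fall, in the first response were C3AR1 (-3.41), CHRNA9 (-2.92), TNFAIP6 (-4.17), SFTPB (-3.66), PDGFRA (-2.88), IL13RA2 (-2.09), MEFV (-2.86), ANXA6 (-0.60) and CNTNAP2 (-0.20). Genes that fell less with the second hairpin were KLK5 (1.68), KLK6 (1.16), KLK7 (2.00), KLK10 (1.61), MUC16 (2.53), EPB41L4A (0.72), GCNT3 (0.57) and CFI (1.52), and genes that rose more with it were SLFN11 (0.80), SCARA3 (1.56) and ADAMTS9 (0.56). Among genes called in opposite directions the differences were UCA1 (3.03), TERT (2.72), E2F2 (2.36), MNS1 (1.93), SLC8A1 (1.85), FPR1 (-3.19), ALOX15B (-2.91), TREM1 (-2.82), ANKS1B (-2.71) and IL1A (-2.51). In 23 of the 32 named genes with a called difference, MIR30A included, the controls themselves differed in the opposite direction, and in 6 by at least as much: MIR30A, CNTNAP2, EPB41L4A, GCNT3, ADAMTS9 and CFI. The differences in these 6 genes may therefore come wholly from the controls, and those in the rest of the 23, such as the KLK genes and IL13RA2, in part. The lists that differed, by their median, were basal mammary markers (-0.44), mesenchymal genes (-0.74), S phase and DNA replication (1.09), G2 and mitosis (0.47), TGF-beta and SMAD targets (-0.26), RAS and MAPK output (-0.21), hypoxia and glycolysis (-0.38), NF-kB and cytokines (-0.92), fatty acid synthesis (-0.34), the unfolded protein and ATF4 response (-0.32), NRF2 targets (-0.28) and fibroblast markers (-1.32), by camera with the preset correlation. With an estimated correlation 5 of these 12 lists held (mesenchymal genes, S phase and DNA replication, G2 and mitosis, fatty acid synthesis and NRF2 targets), and the rest had adjusted p from 0.060 to 0.24. S phase and DNA replication, RAS and MAPK output, NF-kB, fatty acid synthesis, unfolded protein and NRF2 lists were also called between the controls in the opposite direction. These control calls were made by camera with the preset correlation and were lost with an estimated one. For RAS and MAPK output the control median of 0.20 matched the size of the difference, and against both controls pooled the medians were -0.08 and -0.06.

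Replication genes went in opposite directions with the hairpins. If the second response were a weaker version of the first, the signs would match, but 35 of the 37 tested genes of S phase and DNA replication were called in opposite directions. A difference between the control lines was argued against as the whole cause, since the median change from NS1 to NS2 in this list was -0.042 against a difference of 1.09. A different growth state of a line and an off-target action of a hairpin both stay open, as does a difference in the degree of EP300 loss, because there was 1 line per hairpin. An effect of the set on the response, such as one of the vector considered below for MIR30A, cannot be told apart from the hairpin either.

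MIR30A (chromosome 6, 71403551 to 71403621) had 0 reads in NS1, 2 in EP300 KD1, 9304 in NS2 and 3370 in EP300 KD2, so that 99.98% of its reads came from the set numbered 2. Its level of 95.6 CPM in NS2 was at least 3596-fold above the limit set by 3 counts over the NS1 libraries together. Transcription of the surrounding locus was argued against by LINC00472, whose GENCODE gene model spans the region and whose log2 change from NS1 to NS2 was 0.071 ± 0.16 (SE). The other 5 rows of the miR-30 family held at most 28 reads each over all 12 libraries. A candidate explanation is that the vector of set 2 carries its hairpin in a miR-30-based cassette, which the labels do not state. The level in EP300 KD2 was lower than in NS2 (log2 -1.65, edgeR adjusted p = 5.6e-15), and the vector sequence was not analysed here.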

How the results depend on the processing

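Every alternative that gave EP300 a value for each hairpin left its direction and call at the 0.05 threshold as reported. Its log2 changes were -0.70 to -0.66 and -0.90 to -0.83 when single libraries were left out. EP300 changed less than 2-fold with each hairpin, so it did not meet the threshold that required a 2-fold change. It was not tallied for each hairpin under the stricter thresholds, swapped controls or lines as replicates. Over all settings, 293 summary results stayed the same and 22 moved, and of the values for named genes (each hairpin, difference and controls) 2174 stayed the same, 13 lost their call, 1 gained one and 3 reversed. A result tallied as the same need not be identical, since moderate shifts in a count were allowed. Without NS1 replicate 3, for example, 2886 genes differed between the controls in place of 3697. Without a filter on low counts, 12 lists were called for EP300 KD1 in place of 9. Both were tallied as the same. A count was tallied by its total alone, so a shift between higher and lower genes was not tallied as a move. Named values were tallied by direction and call, whatever their size. A change of sign in a named value called in neither setting was tallied as the same. The alternatives with single-accession symbols, library totals and lines as replicates were chosen after seeing the data.

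A required 2-fold change reduced the counts by construction to 1367 (EP300 KD1), 1085 (EP300 KD2), 1068 (average), 766 (difference), 174 (NS2 against NS1) and 673 (shared), and an adjusted p under 0.01 left 2354 genes between the controls. With lines as replicates, and so 2 residual degrees of freedom, 491 genes were called for the average; of 42 named genes whose average was called, 23 kept and 19 lost the call, which is outside the tally above. The correlation of both responses across genes was 0.37 without a filter, 0.72 with at least 1 CPM in 3 libraries, 0.61 with swapped controls, and 0.67 to 0.69 without single libraries; the cause was not tested beyond the change in genes or libraries. With an estimated correlation camera called 5, 7, 3, 5 and 0 lists (EP300 KD1, EP300 KD2, average, difference, controls), against 9, 15, 13, 12 and 11, while fry, which asks another question, called 26, 30, 30, 30 and 17. A call lost in that setting need not mean a higher correlation. For fibroblast markers and fatty acid synthesis the estimates were -0.029 and -0.032, under the preset 0.01. Their camera adjusted p still rose, from 0.0087 to 0.070 (EP300 KD1) and from 0.015 to 0.074 (EP300 KD2).

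Reversed were the second responses of UCA1 (-0.49), E2F2 (-0.014) and IL1A (0.43) against both controls pooled. In each, NS1 and NS2 themselves differed. The 13 lost calls concern UCA1, E2F2 and MIF with the second hairpin and, with library totals alone, the difference in EP300. DESeq2 gave no adjusted p for MIF with the second hairpin, which is therefore not among them.

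In 4 of 18 pairs of libraries with the same replicate number, the deviations from the group means correlated above 0.1 (range -0.11 to 0.27). The median correlation was 0.0076 for same-numbered pairs and -0.019 for pairs of other numbers. Of 12 libraries, 5 correlated best with their own number. The labels do not say whether a number marks a shared culture or batch, and these values cannot exclude it. The replicate block moved the counts to 8748, 7802, 8886, 6858, 3764 and 4406 (EP300 KD1, EP300 KD2, average, difference, controls, shared), and the block within each set to 8612, 7645, 8755, 6692 and 4309 without the controls.

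Depth limited genes near the floor, whose fold changes and differences between hairpins rest on few reads. Examples were C3AR1 in the controls, and ATP6V1B1, PHACTR3, PLEKHS1, KLK10 and MUC16 in the shRNA groups.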

Other observations

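Several lists that the design included were not called by camera for either hairpin, although single members changed with both. By fry, the BCL2 family list was called higher and the Wnt list lower with both hairpins, the stem and progenitor list higher with the first and lower with the second, and the p53, interferon and YAP and TAZ lists lower with the second. The called members gave no such direction with the second hairpin in the stem and progenitor list (6 up and 6 down), the Wnt list (7 up and 7 down) and the YAP and TAZ list (10 up and 11 down). The median log2 changes of these lists were 0.12, 0.04 and 0.01, above 0 where fry called them lower. In the BCL2 family, 4 called members rose and 3 fell with the first hairpin, and 5 rose and 4 fell with the second. Among stem and progenitor genes, HMGA2, a chromatin protein of embryonic cells, rose by 2.78 and 1.29 on the log2 scale with the first and second hairpin, while the drug efflux transporter ABCG2 changed by -2.41 and -1.58. Among YAP and TAZ targets NT5E rose by 2.05 and 1.09 while IGFBP3 changed by -3.79 and -2.88. In the BCL2 family MCL1, which opposes cell death, rose by 1.34 and 0.60. Of the p53 targets, GDF15 changed by -1.09 and -1.22 and SESN2 by -0.84 and -1.05. Among interferon-stimulated genes OAS1 changed by -1.95 and -1.76. In the Wnt list SFRP1, a secreted Wnt antagonist, changed by -0.79 and -0.89. All of these passed edgeR's test in both comparisons.

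A set of genes had replicate libraries far apart although replicates otherwise matched closely. The tests here were written before their results were seen. In 47 genes the highest library of a group was at least 4-fold above the lowest, at a mean of at least 50 counts, in 82 cases of gene and group. HRAS (chromosome 11, 532242 to 535576), the oncogene with which this line was transformed, measured 1.55, 3.55 and 26.9 CPM in EP300 KD2, and 1.93 to 4.90 in the control libraries. MIF, LY6E, EEF1D, U2AF1 and CD99 were further cases. A single faulty library was argued against, since the library most often outlying accounted for 15.9% of cases. Of the 39 such genes with a position that met the mean over all libraries, 35.9% lay within 1 Mb of another, against a median of 5.13% and a 95th percentile of 15.4% in 10000 random sets matched on expression, and 3 of the 4 pseudoautosomal genes that met this mean were among them (two-sided Fisher's exact test, p = 1.7e-07). This fits the hypothesis that reads from regions held more than once in the assembly may have been placed ambiguously, which would make the levels of these genes, HRAS included, unreliable in this table.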
